A study of Drosophila melanogaster with 2 samples.

How the data were processed

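Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, from transgenic flies that carry the protein CG8478 fused to enhanced green fluorescent protein (eGFP). Chromatin was sheared by sonication to fragments of 200 to 800 bp and pulled down with an antibody against GFP, per the labels. There is 1 group with 2 biological replicates, and no second group to compare it with. A control experiment is named in the labels and was not analysed here.

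The deposited data used here are peak lists in the coordinates of genome build dm6, per the file headers. Each peak has a signal value from the authors' peak caller, a score that the authors derived from the irreproducible discovery rate (IDR), and a −log10 q-value per peak as deposited by the authors. The deposited signal has no stated scale, so it was used only to rank and describe peaks within a list. The ranked lists also hold the −log10 of the global IDR, a false discovery measure for peaks that repeat between the inputs of a comparison, and the deposited signal of both inputs. Per the file headers the lists were made from alignments of the libraries and 1 control alignment; the aligner, the peak caller and their versions are not given in the sources used here. Peaks were deposited for each replicate on its own and for both together. For both together there is a conservative list of 2948 entries and a larger list of 3151 entries, called the optimal list here. Replicate 1's own list has 2554 entries and replicate 2's has 2250. The lowest −log10 IDR in the conservative list was 2.0, so the deposited lists were taken as thresholded at an IDR of 0.01.

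From the lists, entries with the same start and end were counted once, with the higher signal kept, and peaks were limited to the 7 main chromosome arms X, 2L, 2R, 3L, 3R, 4 and Y. This left 2904 conservative, 3101 optimal, 2520 replicate 1 and 2225 replicate 2 peaks. Peak ends were checked against the chromosome lengths of the Release 6 genome sequence, and all lay within them. Genes and start sites came from Ensembl release 115. A promoter peak is a summit within 500 bp of an annotated transcription start site. Read counts are not among the values used, so the depth is unknown, and the intervals given cover the counting error of peaks, genes or windows only.

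Overlap of at least 1 bp between replicates was counted with bedtools 2.31.1 and compared with 10000 random placements of replicate 2's peaks on the same arms (one-sided permutation p). For the correlation of signals, ranked entries on the main arms with the same pair of input peaks were counted once, which left 101307 entries, 2788 of them conservative peaks. Summit classes were compared with 10000 sets of random positions outside runs of N (two-sided permutation p). Peak numbers per arm were set against ungapped length and against start sites by exact binomial tests, and log2 ratios there have a pseudocount of 0.5 peaks. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and tRNA and snRNA genes with all other non-coding genes. Log2 odds ratios have 0.5 added to each cell. Of the listed symbols, 5 matched no gene in a unique way and were left out: SA, Mzfp1, nos, calypso and Nelf-B. Motif presence on either strand in the 201 bp around each summit was compared with the 201 bp centred 1000 bp to the right by exact McNemar tests, two-sided, for 18 motifs and for each 8-mer held by at least 10 pairs of windows. Peak numbers in 5 loci were set against the genome mean by exact Poisson tests. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Proportions have 95% Wilson intervals unless said otherwise. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

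The groups, the tests, the gene lists, the motifs, the alternatives and the rule for named genes were fixed before the data were examined, apart from the exact Poisson tests of loci, the choice of the region around CG8478, and the tests and alternatives that the closing section names as chosen later. The rule named CG8478; the genes nearest to the 20 highest conservative promoter peaks that overlap a peak of both replicates; the nearest protein-coding genes of the 5 highest peaks over 500 bp from every start site; for each gene list past the test its 4 bound members with the highest peaks, and for each other list up to 2; and at most 2 peaks in each of the eve, en-inv, Antennapedia complex and bithorax complex loci. Where 2 genes share a promoter, both count as having the peak. Fisher's test treats genes as independent, so the p-values of gene lists may be too small. The gene at 1 of the 20 highest promoter peaks is not reported here.

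The procedures were tested on simulated data. Of 20 simulated gene lists of 50 genes with an odds ratio of 4 among 13968 genes, 18 were recovered, and 0 of 200 lists with no effect were called. With shuffled windows for 2904 peaks, 0 of 18 motifs and 0 of 32872 8-mers were called. Both sets of shuffled windows came from the same flanks, so their base composition was alike. The simulation therefore does not show how a difference in composition between summits and flanks would affect the calls. After an 8-mer was planted in 10% of windows it ranked at the top of the list. A simulated replicate that kept 60% of 2520 peaks gave an overlap of 60.6%.

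The alternatives tried were other overlap rules, promoter windows of 250 and 1000 bp, the optimal list, the upper 50% of peaks by signal, each replicate's own list, a local shuffle within 10 kb, logistic regression with gene length and nearby start sites, a 101 bp motif window, the left flank, and promoters without a peak as background. Scaffolds outside the main arms and the mitochondrial chromosome were left out of the comparisons, because the annotation used there was limited to the main arms.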

Results

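The series holds genome-wide binding profiles of CG8478, tagged with eGFP, in whole embryos of 0 to 24 h. Anti-GFP ChIP-seq was done in 1 group of 2 biological replicates. Whole embryos pool all cell types, and the collection spans all of embryogenesis. The conservative list, made from both replicates, placed 2904 peaks on the main chromosome arms, with a median width of 404 bp. The read depth of the libraries is unknown, since the peak lists hold no read counts.

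The replicates shared most of their peaks. Among promoter peaks chosen for overlap with a peak of both replicates, the highest were at MESK2, Rpn6 and RpL32. Rpn6 is a subunit of the proteasome lid, and RpL32 a protein of the large ribosomal subunit. Of replicate 2's 2225 peaks, 1824 (82.0%, 95% interval 80.3 to 83.5) overlapped a peak of replicate 1, and 1928 of replicate 1's 2520 peaks (76.5%, 74.8 to 78.1) overlapped a peak of replicate 2. Random placement gave a mean of 1.08% and at most 2.02% (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Placement within 10 kb of each peak gave a mean of 5.35% and at most 7.24%. Peaks without a partner were mostly low: 91.9% of the 592 in replicate 1 and 95.5% of the 401 in replicate 2 ranked below the median signal of their list. Of the conservative peaks, 1848 (63.6%, 61.9 to 65.4) overlapped a peak in both replicates' own lists and 514 (17.7%, 16.4 to 19.1) overlapped none.

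The MESK2 promoter peak had input signals of 1042.77 and 1150.76 in the 2 inputs of the between-replicate comparison, from 1 replicate each, and the Rpn6 peak 727.92 and 759.79. Over the 101307 ranked entries on the main arms with distinct pairs of input peaks, nearly all of which lie below the authors' threshold, Spearman's rho between the input signals was 0.25 and Pearson's r of the log2 signals was 0.39. Across 2788 conservative peaks rho was 0.82 and Pearson's r was 0.85, with a standard deviation of the log2 ratio of 0.58, and among the upper 50% of ranked entries by mean signal rho was -0.10. Both subsets were chosen on the values being compared: the conservative list keeps peaks whose ranks repeat between these inputs, which raises the correlation by construction, and choosing on the mean signal lowers it. These correlations are across peaks, which are not independent replicates.

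**Figure D1:**
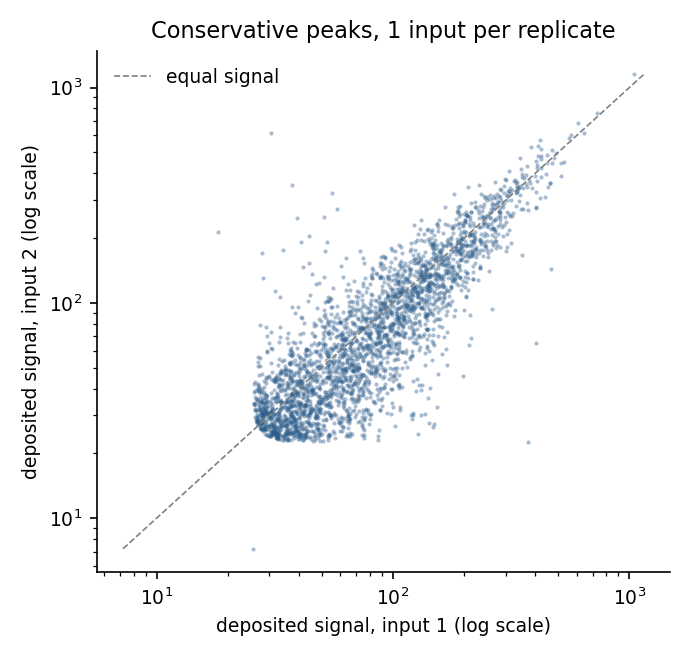
Deposited signal of conservative peaks in the 2 inputs of the between-replicate comparison, 1 input per replicate, both axes on a log scale, with a dashed line at equal signal. Each of the 2788 points is a peak of a list chosen for ranks that repeat between these inputs, which raises Spearman's rho (0.82, against 0.25 over the 101307 ranked entries) by construction.

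Summits were found mainly at promoters. Those within 500 bp of a start site made up 2577 of 2904 (88.7%, 87.5 to 89.8), against a mean of 13.6% for random positions on the same arm and 26.2% for random positions within 10 kb of each summit. Introns held 4.30% of summits against 39.5% at random, intergenic sequence 4.24% against 27%, coding exons 1.76% against 13.1% and 3' UTRs 0.723% against 5.09%. The promoter share differed from both with a two-sided permutation p = 0.0002, the smallest that 10000 sets can give. The classes add up to one total, so the high promoter share lowers the others by construction. Of the 327 summits outside promoters, 125 were in introns, 123 in intergenic sequence, 51 in coding exons and 21 in 3' UTRs. The coding exon share was 0.317% in replicate 1's own list and 1.08% in replicate 2's, and that of 3' UTRs was 0.675% and 0.315%. Over all alternatives, which include the upper 50% of peaks by signal and other promoter windows, the share ran from 0.0% to 2.34% for coding exons, 0.207% to 0.895% for 3' UTRs, 1.10% to 5.10% for introns and 1.58% to 6.03% for intergenic sequence. Promoter summits lay at a median position of -34 bp from the start site, and 80.3% were within 100 bp of it. The nearest start site belonged to a protein-coding gene for 2372 promoter peaks and to a tRNA gene for 144. In all, 3152 of 13968 protein-coding genes (22.6%) had a promoter peak.

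**Figure D2:**
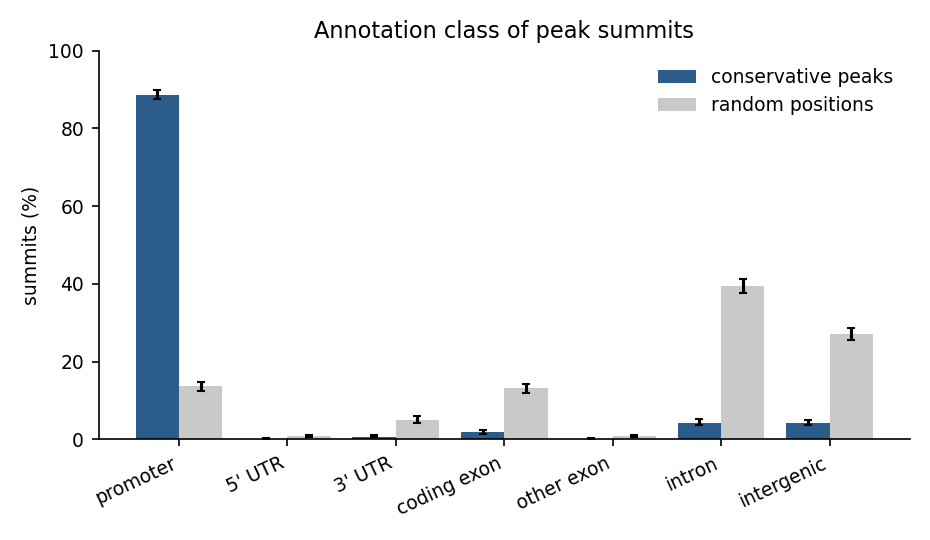
Percentage of 2904 conservative summits (blue, 95% Wilson interval) and of random positions (grey, mean and central 95% of 10000 sets) in each annotation class. Promoters hold 88.7% of summits and 13.6% of random positions, which leaves less of the total for the other classes.

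The 20 highest promoter peaks had signals of 888.28 to 2181.38, and their summits lay 9 to 159 bp upstream of the start site. MESK2 (2R, peak at 21501717 to 21502249) had the highest signal, 2181.38. Among the next were Rpn6 (2R, 14752167 to 14752610) with 1507.04 and RpL32 (3R, 30046051 to 30046477) with 1288.32. Capr, the fly Caprin, an RNA-binding protein, had 1164.84. The uncharacterised CG11857 had 1129.89, Daxx, a relative of a histone chaperone, had 1002.93, and Mic26-27, of the mitochondrial contact site complex, had 989.56. SMC1, a cohesin subunit, had 983.13, Creld 970.9, CG8613 956.96, and Sumo, the ubiquitin-like modifier, 949.94. The endoplasmic reticulum protein jagn had 942.4, mi 932.9, and mtSSB, the mitochondrial single-stranded DNA binding protein, 930.68. Pp2A-29B, the scaffold subunit of protein phosphatase 2A, had 929.74, and bun, of the TSC22 family, had 929.25. CG2924 had 915.32, CG11030 had 893.23 and the sorting nexin Snx27 had 888.28.

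Away from start sites, the highest peak was intronic and 2509 bp downstream of the start site of org-1, a T-box transcription factor gene (X, 8452180 to 8452523), with a signal of 612.82 and unequal input signals of 466.61 and 144.21. The next were in the 3' UTR class nearest to CG16989 (X, 796389 to 796682; 490.65), in intergenic sequence nearest to CG5273 (X, 758832 to 759122; 467.55), in an intron nearest to zf30C, a zinc finger gene (2L, 9758956 to 9759255; 410.88), and in intergenic sequence nearest to CG15468 (X, 4955981 to 4956257; 401.55). Of these 5 peaks, 4 were on X.

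X held 572 peaks (19.7%, 18.3 to 21.2), more than its 17.1% of ungapped length (log2 ratio 0.20, adjusted p = 7.49e-04) and its 16.5% of start sites (log2 ratio 0.26, adjusted p = 3.68e-05, exact binomial tests). Arm 2R held 21.1% of peaks and 18.4% of length (exact adjusted p = 7.49e-04), and 3L held 18.1% of peaks and 20.4% of length (exact adjusted p = 0.00282). The small, largely heterochromatic arm 4 had 16 peaks (log2 ratio to length -0.77, exact adjusted p = 0.0247), and the Y had 2 (log2 ratio -4.85, adjusted p = 5.78e-28), with 1 in replicate 1's own list and 0 in the upper 50% of peaks by signal. These tests took no account of how uniquely reads map to each arm or of its copy number in the embryos. Against start sites, X was higher, 2L (log2 ratio -0.13, exact adjusted p = 0.0415) and Y (log2 ratio -2.47, adjusted p = 7.45e-04) were lower, and no other arm passed. The calls for 3L and 4 against length were lost in the upper 50% of peaks by signal (exact adjusted p = 0.051 and 0.316) and in replicate 2's own list (0.0851 and 0.0913), and in replicate 1's own list arm 4 turned direction (log2 ratio 0.115, adjusted p = 0.76). The log2 ratio of 3L to length was -0.17 over all peaks and -0.17 in the upper 50%. That subset has only 1452 peaks, so a call lost there need not mean a smaller difference. Over all alternatives the exact adjusted p ran from 0.00254 to 0.0851 for 3L and from 0.0335 to 0.76 for 4, and the log2 ratio of 2L to start sites from -0.25 to -0.15.

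Genes of splicing, the cell cycle, chromosome architecture, ribosomes, translation, the proteasome, transcription and oxidative phosphorylation had promoter peaks more often than other protein-coding genes. Of 23 lists tested, 12 had promoter peaks more often than other genes and 2 less often. The lists were not matched with the other genes for expression. Differences in either direction may therefore reflect the kinds of promoters compared rather than the function of the genes. Splicing genes had peaks at 23 of 33 members (69.7%, odds ratio 7.94, adjusted p = 4.81e-08, Fisher's exact test as for all lists), with the highest at SmE (495.97), SF2 (479.31), SmD3 (424.63) and Sf3b1 (395.44), of which SmE and SmD3 belong to the Sm ring of the spliceosome. Cell cycle and replication genes had peaks at 27 of 45 (odds ratio 5.18, exact adjusted p = 2.67e-07), led by aurA, the Aurora A kinase (587.15), PolA1, the catalytic subunit of DNA polymerase alpha (485.26), Mcm5, of the replicative helicase (466.36), and geminin, an inhibitor of origin licensing (462.43). Architectural proteins had peaks at 16 of 27 (59.3%, odds ratio 5.01, exact adjusted p = 1.09e-04), with SMC1 followed by Cap-H2, a condensin subunit (795.0), fs(1)h, a bromodomain protein (377.08), and mod(mdg4), an insulator protein (311.35). In the upper 50% of peaks by signal the odds ratio was 4.55 for splicing genes (14 of 33, log2 2.20) and 7.72 for architectural proteins (15 of 27, log2 2.94).

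Cytoplasmic ribosomal protein genes had peaks at 48 of 86 (55.8%, odds ratio 4.39, exact adjusted p = 1.30e-10), with RpL32 ahead of RpL26 (742.74), RpS2 (733.18) and RpS7 (588.53). Mitochondrial ribosomal protein genes had peaks at 32 of 73 (43.8%, exact adjusted p = 1.29e-04), led by mRpL4 (667.49), mRpL17 (650.72), mRpL39 (515.06) and mRpS17 (357.6). Translation factors had peaks at 33 of 70 (47.1%, exact adjusted p = 2.81e-05), among them the initiation factor genes eIF3c (832.97), eIF3a (559.79), eIF3f1 (547.14) and eIF2gamma (534.79). Proteasome genes had peaks at 23 of 48 (47.9%, exact adjusted p = 3.44e-04), with Rpn6 ahead of Rpn10 (731.62), Prosbeta2 (515.06) and Prosalpha7 (412.09). Transcription machinery genes had peaks at 33 of 72 (45.8%, exact adjusted p = 3.66e-05), led by the Mediator genes MED7 (795.0) and MED27 (513.6), Taf7 (541.49) and Polr2J (382.39). Oxidative phosphorylation genes had peaks at 32 of 86 (37.2%, exact adjusted p = 0.00496), with COX6B (475.99), UQCR-14 (464.34), ND-SGDH (430.09) and COX7A (391.85) highest. Dosage compensation and sex genes had peaks at 9 of 19 (47.4%, exact adjusted p = 0.0372), led by msl-1, a scaffold of the male-specific lethal complex (468.29), her (300.48), gro, a corepressor (124.78), and mof, a histone acetyltransferase (121.53). MED7 and Cap-H2 share 1 peak, as do mRpL39 and Prosbeta2. With each peak given to its nearest start site only, some calls were at their weakest over all alternatives. The exact adjusted p was then 0.0341 for transcription machinery, 0.0179 for oxidative phosphorylation, 0.0136 for translation factor and 0.00139 for architectural protein genes. For dosage compensation and sex genes it was 0.00296, their lowest. In replicate 2's own list the calls for mitochondrial ribosomal protein genes (log2 odds ratio 0.83 against 1.44, exact adjusted p = 0.0612) and for dosage compensation and sex genes (0.201) were lost, and in the upper 50% by signal those for proteasome genes (log2 odds ratio 1.08 against 1.67, 0.0694) and for dosage compensation and sex genes, which turned direction (log2 odds ratio -0.19, adjusted p = 1). The last call was also lost with a 1000 bp window (exact adjusted p = 0.0521) and in the logistic regression (likelihood ratio test, 0.069). Over all alternatives the adjusted p, from exact tests except in the logistic regression, ran from 3.45e-06 to 0.0612 for mitochondrial ribosomal protein, 4.27e-05 to 0.0694 for proteasome and 0.00296 to 1 for dosage compensation and sex genes, and the log2 odds ratio of transcription machinery genes from 0.95 to 1.72.

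The highest odds ratio was that of tRNA genes, which had promoter peaks at 189 of 290 (65.2%) against 3.58% of other non-coding genes (odds ratio 50.4, 95% interval 37.0 to 68.6, exact adjusted p = 1.95e-156). Neighbouring tRNA genes can count the same peak, and 144 promoter peaks were nearest to a tRNA start site. Fisher's test treats the genes as independent, so this interval and p may be too narrow. The log2 odds ratio was 5.65, with 5.02 in replicate 2's own list, 5.75 in replicate 1's and 4.94 with a 1000 bp window. The highest were at tRNA:Leu-AAG-1-3 (2R, 17145260 to 17145503; 350.01), at tRNA:Gly-TCC-1-2 (3R, 7130867 to 7131210; 321.24), and at a peak with the start sites of tRNA:Arg-ACG-1-1 and tRNA:Lys-CTT-1-1 (2R, 6142164 to 6142475; 318.18). Among snRNA genes 7 of 32 had peaks (21.9%, against 7.96% of other non-coding genes, odds ratio 3.24, exact adjusted p = 0.0213), with snRNA:7SKa (365.06), snRNA:U6:96Ac (203.39), snRNA:U6:96Aa (116.27) and snRNA:U5:63BC (106.41) highest. For snRNA genes, the other non-coding genes include the tRNA genes, which raise the share that snRNA genes are compared with. The snRNA call was lost in replicate 2's own list (exact adjusted p = 0.0646), in the upper 50% by signal (0.728) and in the logistic regression (likelihood ratio test, 0.0819), and its adjusted p ran from 0.00234 to 0.728 over all alternatives.

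Chemosensory receptor and cuticle protein genes had promoter peaks less often than other protein-coding genes. Chemosensory receptor genes had peaks at 2 of 230 (0.87%, odds ratio 0.029, exact adjusted p = 6.26e-22), Ir31a (188.69) and Ir60e (137.91), at 0 with a 250 bp window or with nearest start sites only, and cuticle protein genes at 0 of 120 (upper 95% bound of the odds ratio 0.106, adjusted p = 6.63e-13), with 1 in a 1000 bp window. In the upper 50% by signal the log2 odds ratio of chemosensory receptor genes was -3.92, against -4.76 over all peaks. The remaining 9 lists did not pass. Polycomb and trithorax genes had peaks at 11 of 27 (exact adjusted p = 0.0539), with kis, a chromatin remodeller, at 527.13 and Asx at 352.09. Hox complex genes had 3 of 12 (bcd, 100.79, and abd-A, 75.06, highest), segmentation genes 3 of 28 (smo, 246.88; hry, 70.01), and neural genes 5 of 26 (robo1, 242.76; comm, 77.66). Muscle genes had 5 of 26 (mys, 377.08, in a peak shared with fs(1)h; Mef2, 241.32), blood genes 2 of 15 (Hml, 89.26; ush, 71.85), germ line genes 4 of 15 (tud, 179.68; gcl, 123.92), heat shock genes 6 of 24 (DnaJ-1, 694.18; Hsp110, 646.06), and gut and fat body genes 0 of 13 (exact adjusted p = 0.0715). Polycomb and trithorax genes passed in replicate 1's and replicate 2's own lists (exact adjusted p = 0.0432 and 0.0451), in the optimal list (0.00898) and with a 250 bp window (0.0192), with a range of 0.00898 to 0.173 over all alternatives. In replicate 1's own list segmentation genes passed as lower (exact adjusted p = 0.0432, range 0.0432 to 0.817) and Hox genes turned direction (log2 odds ratio -2.60).

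**Figure D3:**
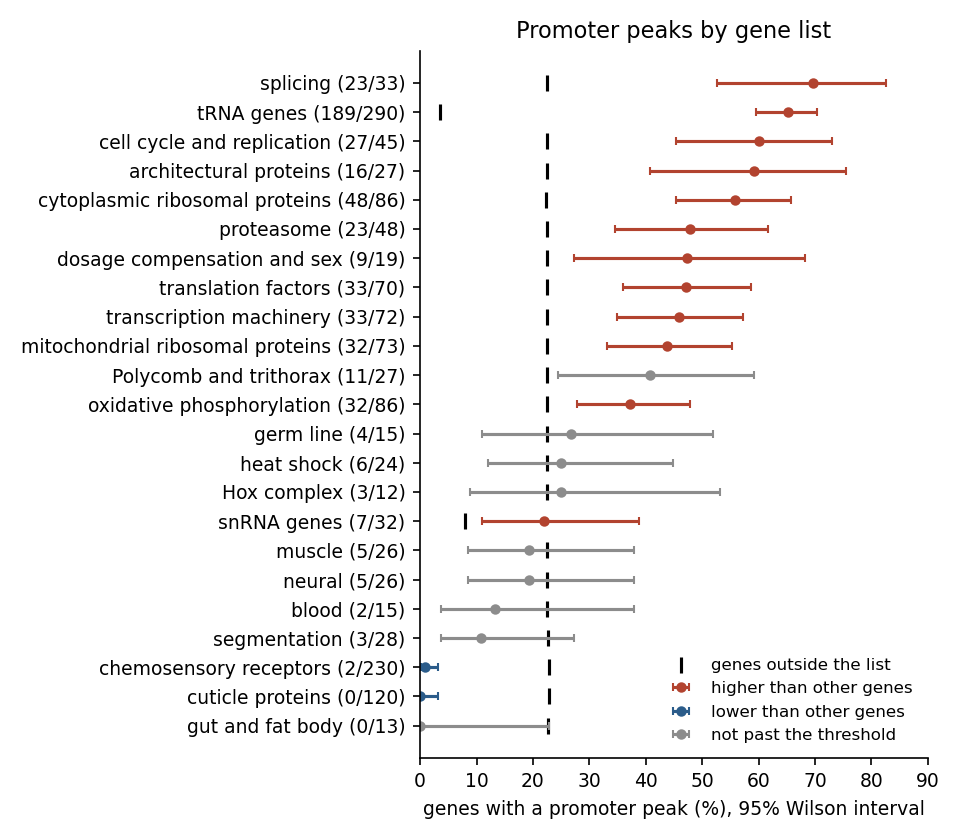
Percentage of genes in each list with a promoter peak (points, 95% Wilson interval; counts in parentheses) and of genes outside the list (vertical ticks; other non-coding genes for tRNA and snRNA genes, other protein-coding genes otherwise). Colours give the call by Fisher's exact test with adjusted p at most 0.05: 12 lists higher, 2 lower and 9 not past the threshold.

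At 4 developmental loci peak numbers did not differ from the genome mean past the threshold. That mean depends on the length of a locus only and takes no account of its start sites, where most summits lie. The mean gave 0.88 peaks for the eve locus and 1.14 for en-inv, so a shortage there could not pass the test. For the Antennapedia and bithorax complexes it gave 7.16 and 6.69. In the upper 50% by signal these complexes held 0 peaks each, against 3.58 and 3.34 (exact Poisson test, adjusted p = 0.118 for both). The eve locus with 20 kb on either side had 1 peak, at the promoter of TER94 (562.83), and the en-inv region had 0. The Antennapedia complex had 4 peaks, the highest at the bcd promoter and in an intron of lab (96.91). The bithorax complex had 7, the highest in introns near mir-iab-8 (120.85) and lncRNA:iab8 (78.74). The replicates' own lists held 1 to 5 peaks in the Antennapedia complex, 2 to 4 in the bithorax complex, 0 to 2 in en-inv and 2 to 3 around eve. The region within 20 kb of CG8478 itself (3R, 9743650 to 9786135) had 6 peaks against 0.9 at the genome mean (exact Poisson test over 5 loci, two-sided, adjusted p = 0.00344). That call was lost in replicate 2's own list (3 peaks, exact adjusted p = 0.329) and in the upper 50% by signal (3 peaks, 0.109), with a range of 8.16e-06 to 0.329 over all alternatives. The peak within 500 bp of the CG8478 start site (3R, 9763085 to 9763305, signal 318.28) had its summit 459 bp from that site and lay closer to Snap24, at -41 bp. Peaks near RpS29 (451.77) and CG12948 (371.29) were the highest in that region. Snap24, RpS29 and CG12948 were chosen after their values were seen.

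**Figure D4:**
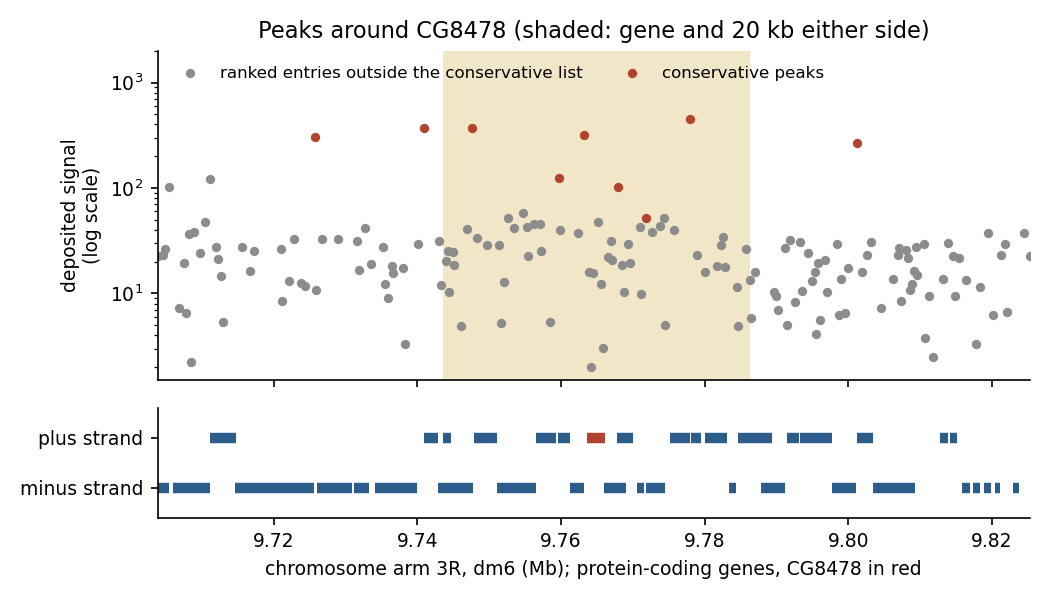
Deposited signal (log scale) of ranked entries along chromosome arm 3R around CG8478, with conservative peaks in red, other entries in grey, the gene with 20 kb on either side shaded, and protein-coding genes by strand underneath. The shaded region holds 6 conservative peaks, and the grey entries there have a median signal of 23.8.

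At the sequence level, summits were marked by TATCGA, the core recognised by the insulator protein BEAF-32, and by the DNA replication-related element TATCGATA, bound by Dref. TATCGATA contains TATCGA, so every window with TATCGATA also has TATCGA. The results for these sequences are therefore not separate, and matches were not assigned to either protein. TATCGA was within the window around 1675 of 2904 summits (57.7%, 55.9 to 59.5) and of 7.65% of flanks, a difference whose p is too small to be held as a number. TATCGATA was at 27.3% of summits and 0.689% of flanks (adjusted p = 1.10e-208, exact McNemar test). Promoter motif 7 (CAKCNCTR) was at 30.3% and 7.3% (exact adjusted p = 5.66e-112), and motif 1, bound by M1BP, was at 7.85% and 0.792% (exact adjusted p = 1.70e-45). Motif 5 (5.54% and 1.52%), motif 6 (8.37% and 3.48%), the TATA box (11.7% and 6.72%), the CTCF core (3.51% and 2.20%) and the Pho core (2.41% and 1.24%) were also higher at summits. The TAGteam sequence of Zelda (0.861% and 1.62%, exact adjusted p = 0.0209) and the GATA site (3.62% and 5.06%, adjusted p = 0.0154) were lower. The other 7 motifs, GAGA, Su(Hw), the initiator, the CACGTG E-box, STAT, AP-1 and the homeodomain site, did not pass. In replicate 2's own list the TAGteam (exact adjusted p = 0.172) and GATA (0.0866) calls were lost and the initiator (0.0409) and the homeodomain site (0.0257) were higher, and in replicate 1's own list the TAGteam (0.108) and CTCF (0.191) calls were lost and the homeodomain site was higher (0.00215). Over all alternatives the exact adjusted p ran from 0.002 to 0.582 for TAGteam, 4.22e-08 to 0.158 for GATA, 1.29e-04 to 0.429 for CTCF, 7.13e-04 to 0.285 for Pho, 5.71e-20 to 0.88 for the initiator, 0.00215 to 0.814 for the homeodomain site, 0.00959 to 1 for GAGA and 6.04e-10 to 0.104 for the TATA box. The difference between summits and background ran from 14.1 to 33.4 percentage points for motif 7, 3.82 to 7.60 for motif 1, 1.62 to 4.63 for motif 5 and 2.03 to 5.30 for motif 6.

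Set against promoters without a peak, the leading motifs kept their difference. These promoters were drawn at random from start sites of any gene type, outside the Y and over 1000 bp from every summit. Their windows had the same offsets from the start site as the summits. They were not matched for the kind of gene or its expression, so the differences may reflect the kinds of promoters compared. TATCGA was at 61.7% of promoter summits and 10.1% of other promoters, TATCGATA at 29.4% and 1.71%, and motif 7 at 31.6% and 8.34% (adjusted p = 1.12e-100, Fisher's exact test). The initiator was lower at promoters with a peak (17.1% and 27.9%, exact adjusted p = 5.71e-20), as were GAGA (3.10% and 4.66%, adjusted p = 0.00959, and -0.27 points against flanks in replicate 2's own list) and the GATA site (3.69% and 7.29%, adjusted p = 4.22e-08). The homeodomain site was higher (12.1% and 9.93%, exact adjusted p = 0.0259), whereas a shorter window against flanks turned its direction (-0.28 points). The TATA box turned direction (12.2% and 14.0%, exact adjusted p = 0.104), and the calls for the CTCF core (0.153), the Pho core (0.0853) and TAGteam (0.582) were lost against this background. Among the 20 highest promoter peaks, 18 had TATCGA; the exceptions were Mic26-27 and mi. The share of summits with TATCGA rose with signal quintile, from 21% (17.9 to 24.5) in the lowest through 48.5%, 65.2% and 74.0% to 79.7% (76.2 to 82.8) in the highest.

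**Figure D5:**
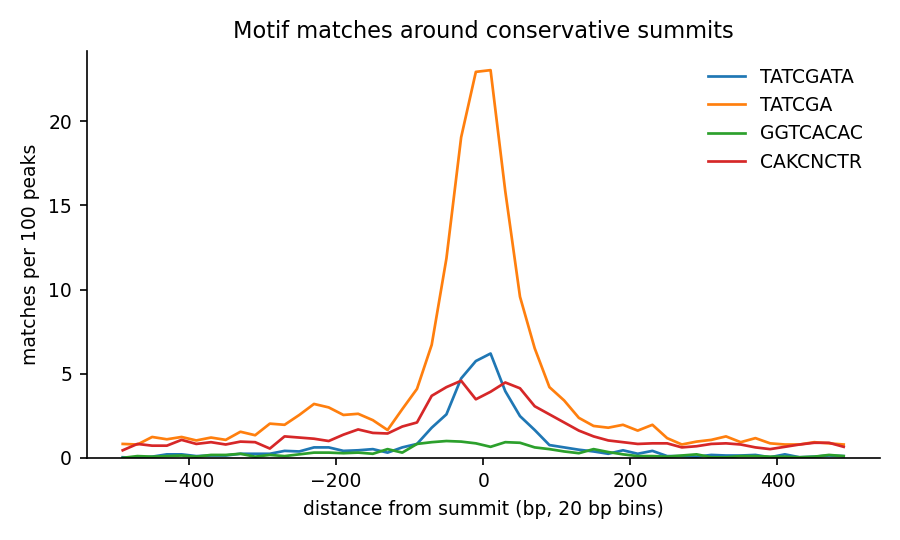
Matches of 4 sequences on either strand per 100 conservative peaks, in 20 bp bins of the distance from the summit (bp). TATCGA has its maximum at the summit, TATCGATA is also centred there, CAKCNCTR and GGTCACAC are also more frequent near it than farther away, GGTCACAC with at most 0.999 matches per 100 peaks in a bin.

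The open search over 31315 8-mers found 1107 higher and 1185 lower at summits. The lowest p was that of ATCGATAG, in 26.8% of summit and 0.517% of flank windows (exact adjusted p = 2.63e-213). The group it heads, of called 8-mers that share 6 or more bases in a row with it, numbers 95. TATCGATA was in slightly more summit windows (27.3%, and 0.689% of flank windows). Other leading groups were headed by AAATATCG (8.78% and 0.654%), CATCTCTA (6.92% and 0.344%), GGTCACAC (7.85% and 0.792%), CGATAACA (6.51% and 0.551%), AAACATCG (6.27% and 0.62%), CGATACTA (4.34% and 0.275%) and CAGCCCTG (3.79% and 0.241%). The next was AATTTAAA (8.92% and 2.755%). Many of these are not separate from the motifs above. AAATATCG, CGATAACA and CGATACTA hold CGATA, a part of TATCGATA, on 1 of their strands. CATCTCTA and CAGCCCTG match motif 7, and GGTCACAC is motif 1. Of the 1107 higher 8-mers, 194 hold ATCGAT, TATCGA or CGATA. Against promoters without a peak, 532 8-mers were higher, of which 440 were among the 1107, and 152 were lower. In the upper 50% by signal 772 were lower. The difference between summits and flanks was there 10.2 percentage points for CATCTCTA, against 6.58 over all peaks, 9.71 against 5.65 for AAACATCG and 7.37 against 4.06 for CGATACTA.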

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

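The tests of mitochondrial coverage, of TATCGA at tRNA genes, and of background signal and start sites around CG8478 were chosen only after the result was seen. Replicate 1's own list holds 16 entries on the mitochondrial chromosome, in 10 distinct intervals that the comparisons leave out; the optimal list holds 6 such entries, and replicate 2's list and the conservative list hold 0. Their signals in replicate 1 run from 763.9 to 8656, while the highest peak of that list on the main arms has 1043. The intervals cover 36.3% of the mitochondrial chromosome, all between bases 7 and 11633 of 19524. Reads from abundant mitochondrial DNA stay open, as the rest has no entry. Only the summit of the highest entry in each interval was searched for TATCGA. Of these 10 summit windows, 0.0% hold it (exact upper 95% bound 30.9%, against 57.7% of nuclear summits). This argues against binding at that sequence at the summits searched. Why replicate 2's list has none stays open, and apart from binding at TATCGA no biological explanation was tested.

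The conservative list also has 30 intervals on 23 scaffolds outside the main arms, which no comparison uses, with a median signal of 77.1. A further 166 ranked entries pass the lowest IDR of the conservative list but are left out of it, 107 of them on the main arms and 50 of those on 3R; the reason is not given in the sources used here.

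Peaks at tRNA genes could come from reads that fit several identical copies, from nearby protein-coding promoters, or from the TATCGA sequence. Of 52 tRNA genes whose sequence occurs once among tRNA genes, 50% (36.9 to 63.1) had a promoter peak, against 3.58% of other non-coding genes. The prediction from shared reads, a share like that of other non-coding genes, thus failed. The test cannot exclude shared reads, because genes that are nearly identical count as single copies. A summit within 500 bp may also belong to a neighbouring tRNA gene. Genes with identical copies had 68.5% (62.3 to 74.1), so shared reads stay open. Of tRNA genes with no protein-coding start site within 1 kb, 61.6% (54.9 to 67.9) had a peak, which argues against spill from such promoters. TATCGA was at 11.1% (6.96 to 17.3) of summits nearest to a tRNA gene and 65.6% of those nearest to a protein-coding gene, which argues against that sequence as the main route. A pull-down of highly transcribed open genes stays open. The authors' lists were made with 1 control alignment, but the control experiment was not analysed here. Apart from binding at TATCGA, no biological explanation was tested.

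Around CG8478, 52 ranked entries that are not conservative peaks had a median signal of 23.8, at percentile 99.1 of 2900 windows of the same size with at least 10 such entries, whose median is 15.6. Both inputs were raised there, to 17.4 and 15 from 9.96 and 9.22 over all such entries on the main arms. Extra copies of the locus carried by the tagged transgene may raise this background. Given the 32 start sites in the region, 3.86 peaks would be there at the rate of arm 3R, and 6 were seen (exact Poisson test, one-sided p = 0.194), so a stretch dense in start sites is also consistent with the peak number. Both explanations stay open, and binding of the protein at its own gene was not tested apart from them.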

How the results depend on the processing

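The alternatives without entries that share a replicate peak with a higher entry, those that gave each peak to its nearest start site only, and all of those for loci were chosen after seeing the data. Of 43 alternative values for the main results, 38 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. Replicate overlap ranged from 67.5% to 88.3% under other rules, and the promoter share from 85.1% to 97.0%. The Spearman correlation of signal between replicates moved from 0.25 to 0.82 for conservative peaks, which are chosen for ranks that repeat and so raise it by construction, and reversed to -0.10 for the upper 50% by mean signal, a choice on the sum of both signals that lowers it by construction. The number of arms past the threshold against length was 5, and 3 for the upper 50% by signal; without a replicate it was 3 to 4. Higher 8-mers numbered 1107, and 532 against promoters without a peak; lower 8-mers numbered 1185, 772 in the upper 50% and 152 against promoters. For these counts and the reversals that follow, the cause was not tested. In the upper 50%, 2L had log2 -0.069 to length, 3R 0.004 to length and 0.019 to start sites, Hox genes -2.03, germ line genes -0.66, dosage compensation and sex genes -0.19, and GAGA -1.24 points. Without a replicate, the values were -0.03 to -0.028 for 2L to length, -0.039 to 0.031 for 3R to length, -0.024 to 0.046 for 3R to start sites, -0.679 to 0.115 for arm 4 to length, -0.348 to 0.445 for arm 4 to start sites, -2.604 to 0.675 for Hox genes, and -0.27 to 0.079 points for GAGA. Without shared entries 3R had 0.011 to start sites. Hox genes had -0.37 in the optimal list and -0.094 in the logistic regression, where germ line genes had -0.054. A 250 bp window gave 0.055 for neural and 0.055 for muscle genes, and nearest start sites only gave 0.44 and 0.081. Against promoters without a peak, GAGA had -1.55, Su(Hw) -0.039, TATA -1.75, the initiator -10.8 and AP-1 -0.47 points. The left flank gave -0.24 for the initiator and -0.034 for AP-1, and a shorter window -0.28 for the homeodomain site. Relative to each list's genome mean, the bithorax complex turned from above to below, with 6 peaks in the optimal list, 0 in the upper 50% and 2 to 4 without a replicate, and en-inv had 0 to 2 without a replicate. Of 94 named peaks, 94 were in the optimal list, 80 in the upper 50%, 89 in replicate 2's list and 90 in replicate 1's. The logistic regression gave no value for cuticle and gut and fat body genes, which have 0 bound members, and overlap and rank correlation have no value without a replicate. No paired analysis was possible because there is 1 group only. The depth is unknown.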

Other observations

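The tests below of TATCGA and the CTCF core away from start sites and of U6, 7SK, 7SL, RNase P and RNase MRP RNA genes were chosen only after the result was seen, and that of divergent promoters before. Summits nearest to a tRNA gene lay at a median of 50 bp downstream of its start, where tRNA genes have a median length of 73 bp, while summits nearest to protein-coding genes lay at a median of -38 bp. Their median signals were 129 and 145. Among snRNA genes, peaks were at snRNA:U6:96Aa, snRNA:U6:96Ac and snRNA:7SKa, which RNA polymerase III transcribes, and at snRNA:U1:82Eb, snRNA:U2:34ABb, snRNA:U4:39B and snRNA:U5:63BC, which RNA polymerase II transcribes. Those not already named were chosen after their values were seen.

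The 327 peaks over 500 bp from every start site had a median signal of 69.9, and 149 of them were in the lowest signal quintile of all peaks. On X there were 15.6% (12.1 to 19.9) of them and 20.2% (18.7 to 21.8) of promoter peaks, although 4 of the 5 highest were on X.

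A hypothesis is that peaks away from start sites may form a class with other sequences. TATCGA was at 25.7% of them and 61.7% of promoter peaks, and within signal quintiles the Mantel-Haenszel odds ratio was 0.397 (95% interval 0.298 to 0.529). The CTCF core was at 9.79% (7.02 to 13.5) of them and 2.72% (2.16 to 3.42) of promoter peaks (odds ratio 3.89, two-sided Fisher's exact p = 2.05e-08, not matched for signal), and within signal quintiles the Mantel-Haenszel odds ratio was 3.12 (1.94 to 5.02). Another hypothesis is that U6, 7SK, 7SL, RNase P and RNase MRP RNA genes, some of those that RNA polymerase III transcribes, have peaks more often than other snRNA genes, with ribosomal RNA genes not included; 3 of 9 and 4 of 27 had one (two-sided Fisher's exact p = 0.333), and with 9 such genes the test decided nothing either way.

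A further hypothesis is that divergent pairs of protein-coding promoters have a peak more often than 2 single promoters would. Of 1745 pairs with gene starts at most 500 bp apart, 46.5% (44.2 to 48.9) had a peak. Other protein-coding promoters had a peak in 13.7% (13.0 to 14.4), from which 25.5% of pairs would have one if their members were independent. The excess is in line with a preference for divergent promoters, but housekeeping genes were not matched between the pairs and the rest, so it may come from the kinds of genes in pairs.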
